A study of Mus musculus with 18 samples.

How the data were processed

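RNA sequencing was done on tumor cells of the mouse pancreatic tumor lines 6419c5 and 6694c2 (strain C57BL/6) that had grown as subcutaneous implants and were then sorted. Each line had a wild-type (WT) group and 2 clones with a knockout of Kdm3a, which encodes a demethylase of lysine 9 on histone H3. Each of the 6 groups had 3 libraries, 18 in all. Per the labels, total RNA was extracted with a column kit for small samples and the libraries were made by a sequencing company. The labels do not say which surface marker or dye the sort used, how the gene was knocked out, or whether the 3 libraries of a group came from separate animals. The 3 libraries of a knockout group all come from 1 clone, so they measure that clone, and the unit in which a knockout was made is the clone.

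The deposited values are TPM, transcript abundances scaled to a fixed total, for 24493 gene symbols. The name given to the deposited table mentions a batch that the labels do not describe, so whether the values were adjusted between batches, which would change every TPM and fold, is unknown. Per the submitters' processing notes, the authors quantified with Salmon on the mouse build mm10; the Salmon version, the transcript annotation and the way transcripts were summed to genes are not stated. Each of the 18 columns sums to 1e+06 TPM. No value is below 0 and exact zeros are kept. TPM hold no read numbers, so the depth of each library is unknown, no counting interval or detection floor can be given, and no count model was fitted. The deposited columns letter the clones A and B and the sample titles number them KO1 and KO2; A was taken as KO1 and B as KO2, which affects only the names of the clones. Of the 24493 symbols, 23980 are gene names in the GENCODE M21 annotation of build GRCm38, which was used for positions only.

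Values were analysed as log2(TPM + 1) for the 13422 genes with a mean of at least 1 TPM over the 18 libraries. A fold change is on this log2(TPM + 1) scale throughout, which understates the change of genes with low TPM. One linear model of 6 group means (12 residual degrees of freedom) was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a mean-variance trend, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. The contrasts were the mean of the 2 knockout clones minus WT in each line, the same over both lines with equal weight, the difference of the knockout effect between lines (6694c2 minus 6419c5), each clone minus its WT, clone B minus clone A in each line, and WT 6694c2 minus WT 6419c5. Comparisons of 2 clones with the same WT libraries share their chance values. The overlap of independent lists was computed as the product of both numbers of calls over the genes tested. Unchanged groups were simulated 20 times, but almost no gene is called in them, so their overlap says nothing on genes with real changes. A further simulation, added after the result was seen, gave each clone its own changes relative to the residual spread, moved to random genes, and kept the WT libraries shared. It was run with the changes as estimated and with changes shrunk by the variance that library noise adds. Both versions called more genes per clone than the real data, so their overlap is set beside the overlap of independent lists of the same simulated size.

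Gene lists for pathways, cell states and the markers of other cell types (32 lists, 641 of their 644 genes in the table) were written before the data were examined, as were the contrasts, the filter, the threshold and the rule for naming genes. The 31 lists with at least 5 tested genes were tested with camera at its preset correlation between genes of 0.01, adjusted over lists within a contrast; camera with a correlation estimated for each list, and fry, were run beside it. The markers of pancreatic acinar cells were left out of the list tests because fewer than 5 of them were tested. Named genes are, for each knockout contrast over the clones of a line or of both lines, the 10 with the largest rise and the 10 with the largest fall among the called genes with at least 5 TPM in the higher group and the same sign in every clone. For the other contrasts they are the top 5 in each direction. Not every gene that the rule gives is printed. Kdm3a, Egfr, Klf5 and Smad4 are always named, and up to 4 members of each list described. A macrophage index was computed per library as the mean log2(TPM + 1) of 10 macrophage genes.

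The model was tested on simulated data made from the real line means and residual spreads of the 13422 genes, with 100 genes changed 2-fold and 100 changed 4-fold. Of the genes changed 2-fold it recovered 86% in the 6419c5 contrast, 85% in the 6694c2 contrast and 96% over both lines, and of those changed 4-fold 97% in each. Of its calls, 4.2%, 7.6% and 6.8% were unchanged genes. The simulated spread was that between libraries of a group, and the simulated clones of a line did not differ by chance. The real clones of a line did differ from each other. These percentages therefore describe noise between libraries only. They give no rate of recovery or of false calls where clones differ by chance. In the simulated contrast over both lines camera called 3 of 3 moved lists of random genes and 0 of 27 unmoved ones. The members of these lists varied independently, so this gives no rate of false calls for lists of correlated genes. When the real libraries were regrouped at random over both lines, the median number of lists called at the preset correlation was 13. Permutation p-values of correlations across libraries come from 1e+05 permutations, are two-sided, and are adjusted over 3 principal components.

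Alternatives tried were a pseudocount of 0.1, no filter and a mean of at least 5 TPM, median-of-ratios scaling, quantile normalization, removal of the 20 most abundant genes, only the libraries of the groups compared, the replicate number as a block, limma's array quality weights, an adjusted p under 0.01, the clone as the unit, each library left out in turn, the macrophage index as a covariate, and removal of 3 libraries that stood apart in macrophage or endothelial genes. Of the 8746 genes with a mean of at least 10 TPM, 90 are listed at 0 in at least 1 library. Members of families with near-identical copies (Gbp, Tgtp, H2-Q, Ifit3, Reg and Hba genes among them) are uncertain, because quantification can share their reads out differently between libraries. Mir5103, Hba-a2, Mir6395, Mir7013, H2-Q8, Mir142b and Mir212 have both a 0 and more than 5 TPM within 1 group and are uncertain for that reason.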

Results

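Gene expression was measured by RNA sequencing in sorted tumor cells from subcutaneous implants of 2 mouse pancreatic tumor cell lines, 6419c5 and 6694c2. The comparison was between WT cells and cells in which the histone demethylase gene Kdm3a had been knocked out, with 2 knockout clones per line, called A and B here. There were 6 groups of 3 libraries. The files give TPM only, so depth is unknown; between 12213 and 13590 genes had at least 1 TPM per library. Libraries of the same group correlated with each other at 0.932 to 0.989 (Pearson, log scale, across genes) and libraries of other groups at 0.797 to 0.974.

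Kdm3a (chromosome 6, 71588972 to 71632990, minus strand, mm10) was the targeted gene, and its transcript was lower in the knockouts but far from absent. In 6419c5 the WT libraries had 38.2, 24.1 and 32.9 TPM, those of clone A 21.6, 24.6 and 21.6 TPM, and those of clone B 12.3, 18.85 and 13.5 TPM. In 6694c2 the WT libraries had 39.9, 38.9 and 67.65 TPM, those of clone A 26.25, 26.4 and 29.8 TPM, and those of clone B 28.8, 30.2 and 25.2 TPM. All 6 knockout libraries of 6694c2 lay below all 3 WT libraries. On the log2 scale Kdm3a fell by 0.75 (SE 0.13, limma adjusted p = 7.99e-04) over both lines, by 0.75 in 6419c5 (SE 0.18, adjusted p = 0.0185) and by 0.75 in 6694c2 (SE 0.18, adjusted p = 0.0091). Clone B of 6419c5 (-1.04, limma adjusted p = 0.00306) and clones A (-0.76, adjusted p = 0.0172) and B (-0.73, adjusted p = 0.0278) of 6694c2 passed the test alone, and clone A of 6419c5 (-0.45, adjusted p = 0.299) did not. The call in 6419c5 rested on its WT libraries: without WT replicate 1 the change was -0.60 (limma adjusted p = 0.113) and without WT replicate 3 it was -0.71 (adjusted p = 0.0742). In 6694c2 WT replicate 3 had the highest level, and without it the change was -0.49 (limma adjusted p = 0.0464). A knockout by a small deletion or insertion need not lower the transcript, and the deposited gene totals cannot show one.

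Klf5, a transcription factor of epithelial progenitor cells (chromosome 14, 99298691 to 99315036, plus strand), fell in all 4 clones. Its WT level was 102 ± 10.7 TPM (SD, n = 3) in 6419c5 and 99.0 ± 4.08 TPM (n = 3) in 6694c2, and its knockout means were 69.9 ± 5.55 and 63.6 ± 2.43 TPM in 6419c5 and 54.2 ± 2.32 and 67.5 ± 2.42 TPM in 6694c2. Over both lines Klf5 fell by 0.65 on the log2 scale (SE 0.05, limma adjusted p = 2.89e-07). Egfr, the epidermal growth factor receptor (chromosome 11, 16752203 to 16918158, plus strand), differed between the lines. In 6694c2 it went from 20.5 ± 3.57 TPM in WT to 6.90 ± 2.76 in clone A and 5.63 ± 0.133 in clone B (n = 3 each) (-1.59 on the log2 scale, SE 0.18, limma adjusted p = 2.54e-05). In 6419c5 Egfr stood at 19.5 ± 4.26, 22.2 ± 0.824 and 20.7 ± 1.16 TPM and did not pass (0.15, limma adjusted p = 0.767). The difference between the lines in Egfr passed its own test (-1.74, adjusted p = 0.00103). Smad4, a transducer of TGF-beta signals (chromosome 18, 73639009 to 73703780, minus strand), did not pass in 6419c5 (0.03, adjusted p = 0.946), in 6694c2 (-0.18, adjusted p = 0.312) or over both (-0.07, limma adjusted p = 0.604).

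**Figure D1:**
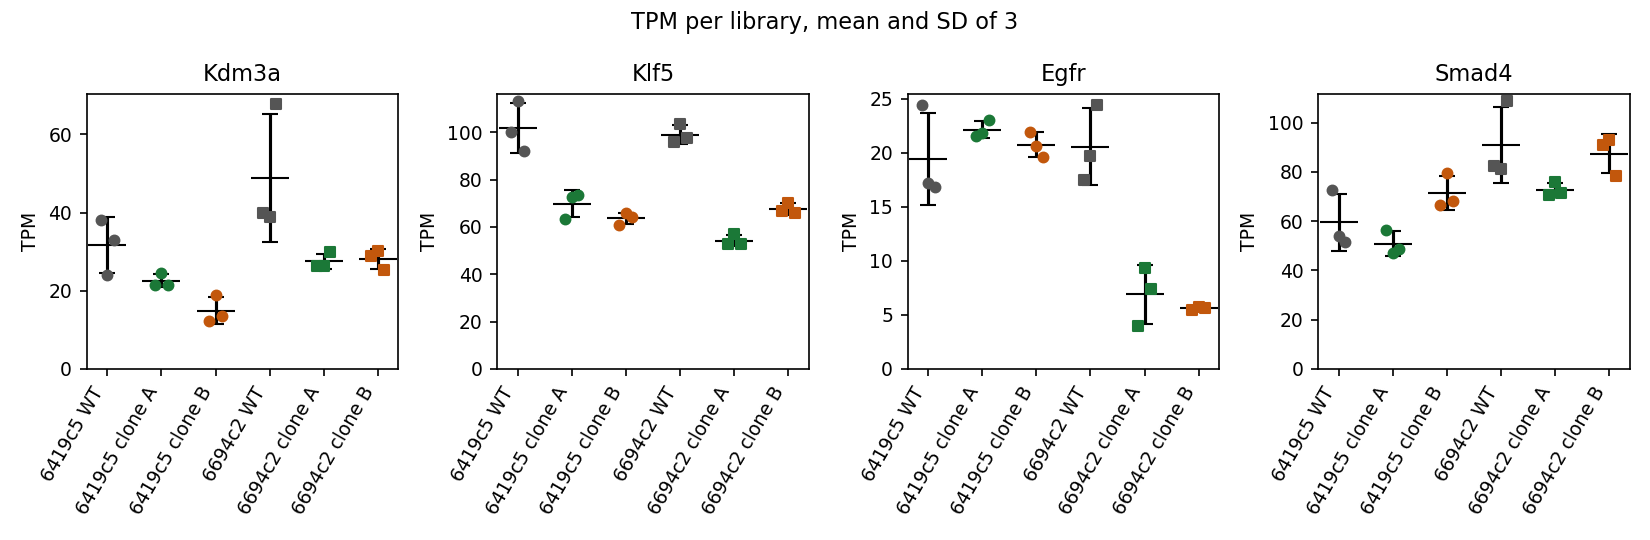
TPM of Kdm3a, Klf5, Egfr and Smad4 in each library of the 6 groups, with the mean and SD of 3 libraries. Klf5 was lower in every knockout group than in the WT of its line, and Egfr only in the knockouts of 6694c2.

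Genes of macrophages, which would not be expected among pure tumor cells, varied widely between libraries. The mean macrophage index was 7.42 ± 1.39 in WT, 8.49 ± 1.04 in clone A and 4.35 ± 0.39 in clone B of 6419c5, and 5.20 ± 1.69, 8.06 ± 0.33 and 5.78 ± 1.75 in the same order in 6694c2 (SD, n = 3). C1qa, a complement gene of macrophages, ranged from 15.3 TPM in 6694c2 WT replicate 3 to 1574 TPM in 6419c5 clone A replicate 2. The second principal component, with 21.99% of the variance, followed the index across the 18 libraries (Pearson r = 0.955, Spearman rho = 0.938, permutation p = 1e-05 for both, the smallest that the permutations can give, adjusted p = 3e-05). Without the 2 libraries farthest from the median of the index r was 0.942, within 6419c5 it was 0.991 and within 6694c2 0.973. The permutations treat the 18 libraries as exchangeable although they form 6 groups. The genes of the index are also among those that made the components, so part of the correlation is built in. For the first component, with 41.0% of the variance, r was 0.232 (permutation p = 0.346, adjusted p = 0.519) and rho 0.488 (permutation p = 0.0415, adjusted p = 0.0622), with r at 0.243 without the 2 farthest libraries and at 0.826 and 0.772 within the lines. For the third, r was 0.109 (permutation p = 0.67, adjusted p = 0.67) and rho 0.181 (permutation p = 0.474, adjusted p = 0.474). Endothelial genes stood out in 6694c2 clone A replicate 1, where Pecam1 was at 43.2 TPM against 7.32 and 5.83 TPM in the other libraries of that clone. The entry Mir6236, annotated as a microRNA gene, alone took from 6.04% to 17.4% of all TPM per library. The deposited values cannot show whether its reads come from a microRNA. As TPM have a fixed total, this share moves the TPM of every other gene.

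The comparison of both knockout clones with WT in 6419c5 asks which genes Kdm3a loss changes in that line. Genes of the interferon response rose most. Ubd, a ubiquitin-like modifier induced by cytokines, went from 0.635 ± 0.372 TPM in WT to 49.7 ± 3.898 in clone A and 14.8 ± 3.32 in clone B (SD, n = 3 each), a rise of 4.13 on the log2 scale (SE 0.20, limma adjusted p = 3.3e-08). The GTPase genes Iigp1 (3.94), Tgtp2 (3.93), Tgtp1 (3.43), Gbp2 (3.33), Gbp4 (3.08), Gvin1 (2.96) and Gbp3 (2.65), the chemokine gene Cxcl9 (3.80) and Ido1 (2.83), which breaks down tryptophan, rose with it. Reg3b fell from 73.7 ± 31.03 TPM to 1.92 ± 0.227 and 2.76 ± 4.21 (-4.72, SE 0.49, limma adjusted p = 1.84e-05). Its relatives Reg1 (-4.26) and Reg3g (-3.28) fell too, as did the gastric genes Gkn3 (-4.19), Gkn1 (-3.12) and Tff2 (-3.06), the tight junction gene Cldn7 (-3.84), the potassium channel gene Kcnk1 (-3.49), the GABA receptor gene Gabrp (-3.23) and the noncoding RNA Dio3os (-2.94).

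By list, 18 of the 21 interferon gamma response genes rose in 6419c5 and none fell. Their median was 1.69 (camera adjusted p = 1.86e-29, 0.0108 with an estimated correlation, 18 rose and 1 fell adjusted over the list alone). Of the 20 genes of MHC class I antigen presentation 17 rose and 1, Calr (-0.27), fell. Their median was 1.13 (camera adjusted p = 1.24e-20, 0.0157 with an estimated correlation, 18 and 1 adjusted over the list alone). H2-Q4 (2.01), the immunoproteasome gene Psmb9 (1.92) and the peptide transporter gene Tap1 (1.89) led them. Of 28 type I interferon response genes 19 rose, 23 adjusted over the list alone, among them Zbp1 (1.70) and Ifit3 (1.59). The call of that list was lost at adjusted p = 0.0523 with an estimated correlation (camera adjusted p = 3.29e-18). In the epithelial list 11 of 19 genes fell (12 adjusted over the list alone, median -0.89, camera adjusted p = 6.86e-15, 0.0324 with an estimated correlation). Cldn7, Cldn4 (-2.47), Cldn3 (-2.23) and Epcam (-2.02) fell most. Of 8 basal-like and squamous genes 5 fell (5 adjusted over the list alone, median -0.78, camera adjusted p = 1.76e-07, 0.0324 with an estimated correlation). The laminin genes Lama3 (-1.86) and Lamb3 (-1.16) were among them. Of 23 genes of the classical pancreatic subtype 10 fell, Agr2 (-2.40), Foxa1 (-2.34) and Spdef (-2.30) among them. Adjusted over the list alone 2 were higher and 13 lower (median -0.49, camera adjusted p = 4.61e-08, adjusted p = 0.0523 with an estimated correlation). Immediate early and dissociation genes, which respond to handling of cells, fell in 11 of 22 cases (13 adjusted over the list alone, median -0.54, camera adjusted p = 1.75e-12, adjusted p = 0.0523 with an estimated correlation). Nr4a1 (-2.08) and Fosb (-1.92) fell most. Of the markers of other cells, fibroblast genes rose in 2 of 20 cases in 6419c5 (2 adjusted over the list alone, median 0.31, camera adjusted p = 0.022, adjusted p = 0.69 with an estimated correlation, median 0.57 with the macrophage index as a covariate). Skeletal muscle genes passed as a list with 0 of 6 called (median 0.68, camera adjusted p = 0.0276, adjusted p = 0.524 with an estimated correlation). Clone A carried both: against WT its fibroblast median was 1.03 (camera adjusted p = 2.44e-07, adjusted p = 0.28 with an estimated correlation) and its skeletal muscle median 1.74 (camera adjusted p = 3.27e-06, adjusted p = 0.134 with an estimated correlation). In clone B they were -0.31 (camera adjusted p = 0.639) and -0.37 (adjusted p = 0.524). In all, 990 genes changed in 6419c5 by limma, 533 higher and 457 lower. Median-of-ratios scaling gave 448 higher and 467 lower, quantile normalization 484 and 466, and removing the 20 most abundant genes 453 and 498. In the same contrast 14 of 31 lists passed at the preset correlation, 4 with the estimated one. With the values as deposited, clone B carried most of the falls: 1470 genes were lower in it and 221 in clone A. Its macrophage genes were also lower than in WT. The balance between the clones depended on the scaling. Clone B had 991 genes higher and 2543 lower than clone A as deposited, but 1985 and 1635 with quantile normalization.

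In 6694c2 the same question gave more changed genes for the mean of the clones, 2744 against 990 in 6419c5. Of the clones tested alone, clones A and B of 6694c2 changed 2913 and 1949 genes, and those of 6419c5 643 and 2540. The counts of single clones thus overlap between the lines. The letters do not match a clone of 1 line to a clone of the other. The clones of 6419c5 differed more from each other (3534 genes) than those of 6694c2 (1279 genes). Genes of MHC class II antigen presentation rose from low levels: Cd74 went from 58.5 ± 51.1 TPM in WT to 2029.9 ± 503 in clone A and 1958 ± 585 in clone B (SD, n = 3 each), a rise of 5.37 on the log2 scale (SE 0.45, limma adjusted p = 7.32e-07). H2-Eb1 (5.43), H2-Aa (5.34) and H2-Ab1 (5.08) rose alike, and so did their transactivator gene Ciita, from 0.387 ± 0.194 to 9.93 ± 2.49 and 13.0 ± 2.68 TPM. Iigp1 (5.06), Cxcl9 (5.01), Tgtp2 (4.70) and the class I gene H2-Q7 (4.51) were among the top rises again. Retnla (5.75, SE 0.77, limma adjusted p = 1.05e-04) and Chil4 (4.61), which alternatively activated macrophages express strongly, were also among them. Their levels spread widely within clones: Retnla was at 421 ± 95.8 TPM in clone A and 116 ± 161 TPM in clone B. Piezo2, a channel opened by mechanical force, fell from 43.4 ± 13.1 TPM to 2.71 ± 0.377 and 0.878 ± 0.282 (-4.04, SE 0.16, limma adjusted p = 6.07e-10). Clic6 (-3.52), Ube2e2 (-3.19), Kctd15 (-3.08), the epithelial adhesion gene Epcam (-3.03), Trib2 (-2.99), Slco3a1 (-2.75), the lactate exporter gene Slc16a3 (-2.71) and the tight junction gene Cldn6 (-2.66) fell with it, as did the uncertain Mir5103 (-3.68).

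The lists moved as follows in 6694c2. Of 21 interferon gamma response genes 19 rose (19 adjusted over the list alone, median 2.66, camera adjusted p = 3e-25, 0.0102 with an estimated correlation). Of 28 type I interferon response genes 27 rose (27 adjusted over the list alone, median 1.84, camera adjusted p = 8.5e-25, 0.0459 with an estimated correlation). Of 20 MHC class I genes 18 rose (19 adjusted over the list alone, median 2.20, camera adjusted p = 2.29e-23, 0.0102 with an estimated correlation). Psmb9 rose by 4.39, Psmb8 by 4.11 and Tap1 by 3.89. Epithelial genes fell in 11 of 19 cases, with 1 higher and 12 lower adjusted over the list alone (median -0.85, camera adjusted p = 1.39e-11, 0.0483 with an estimated correlation). Marveld2 (-2.05) and Ocln (-1.79) were among them. Of 8 basal-like and squamous genes 4 fell and 1 rose, 5 and 1 adjusted over the list alone (median -1.11, camera adjusted p = 6.89e-06, 0.0483 with an estimated correlation). Of 25 hypoxia genes 9 fell, with 1 higher and 10 lower adjusted over the list alone (median -0.17, camera adjusted p = 2.59e-07, 0.0483 with an estimated correlation). Ak4 (-1.85) and Car9 (-1.15) fell most. Of 14 genes of the EGFR family and its ligands 5 fell and 1 rose, 7 and 1 adjusted over the list alone. Beside Egfr, Areg (-1.29) and Erbb3 (-0.98) fell and Nrg1 (0.94) rose (list median -0.29, camera adjusted p = 2.36e-04, adjusted p = 0.0889 with an estimated correlation). Glycolysis genes fell in 6 of 18 cases (8 adjusted over the list alone, median -0.19, camera adjusted p = 3.23e-07, adjusted p = 0.0885 with an estimated correlation). Cholesterol synthesis genes fell in 8 of 22 cases (9 adjusted over the list alone, median -0.31, camera adjusted p = 3.12e-08, adjusted p = 0.142 with an estimated correlation). The medians of these smaller falls in 6694c2 moved with the setting. For the EGFR list the median was -0.11 without the 3 libraries that stood apart (6419c5 WT replicate 3, 6694c2 clone A replicate 1 and clone B replicate 3), -0.08 with the macrophage index as a covariate and -0.47 with median-of-ratios scaling. With that scaling the median was -0.35 for hypoxia, -0.37 for glycolysis and -0.49 for cholesterol synthesis. Quantile normalization gave -0.27 for hypoxia and -0.31 for glycolysis, and removing the 20 most abundant genes gave -0.28 and -0.31.

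Markers of other cells moved in the knockouts of 6694c2 on average, but those of macrophages and fibroblasts not in every library. Clone B replicates 1 and 2 had macrophage indices of 4.76 and 4.79, against 3.50 to 6.87 in WT. Their mean log2(TPM + 1) of fibroblast markers was 2.78 and 2.65, against 2.73 to 2.99 in WT. In clone B only replicate 3 stood above WT in both, at 7.80 and 4.48. Neutrophil genes rose in 10 of 14 cases (11 adjusted over the list alone, median 1.44, camera adjusted p = 1.92e-04, adjusted p = 0.0885 with an estimated correlation). S100a8 rose by 2.63 and Retnlg by 2.58. T and NK cell genes rose in 7 of 9 cases (8 adjusted over the list alone, median 1.64, camera adjusted p = 3.27e-05, adjusted p = 0.0724 with an estimated correlation). Ccl5 rose by 3.39 and Nkg7 by 1.88. Fibroblast genes rose in 11 of 20 cases (16 adjusted over the list alone, median 1.16, camera adjusted p = 5.02e-05, adjusted p = 0.321 with an estimated correlation). Macrophage and dendritic cell genes rose in 8 of 22 cases (11 adjusted over the list alone, median 1.97, camera adjusted p = 8.88e-06, adjusted p = 0.433 with an estimated correlation). Of these last, 4 were the MHC class II genes Cd74, H2-Aa, H2-Ab1 and H2-Eb1. Endothelial genes rose in 5 of 13 cases, with 1 lower (median 1.17, 7 and 1 adjusted over the list alone, camera adjusted p = 0.0461, adjusted p = 0.656 with an estimated correlation). Erythroid genes fell in 4 of 5 cases (5 adjusted over the list alone, median -2.02, camera adjusted p = 2.97e-05, adjusted p = 0.0889 with an estimated correlation). Without the 3 libraries that stood apart (6419c5 WT replicate 3, 6694c2 clone A replicate 1 and clone B replicate 3) the median was 0.53 for endothelial and 0.72 for fibroblast genes. With the macrophage index as a covariate it was 0.235 for macrophage and dendritic cell genes, 0.93 for neutrophil and 0.75 for fibroblast genes. In 6694c2 2744 genes changed by limma, 1967 higher and 777 lower. In the same contrast 21 of 31 lists passed at the preset correlation, 6 with the estimated one. The balance of directions was set by the scaling of the libraries. Median-of-ratios scaling gave 1068 higher and 1664 lower (median of all genes moved by -0.16). Quantile normalization gave 866 and 1614 (median moved by -0.20), and removing the 20 most abundant genes gave 1331 and 1194. No list member called in a knockout contrast changed its direction under these scalings.

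Over both lines, with equal weight, the interferon and MHC class I lists rose and the epithelial list fell. Iigp1 rose by 4.50 (SE 0.28, limma adjusted p = 3.88e-08), from 6.03 ± 6.45 TPM in WT of 6419c5 to 79.1 ± 8.31 and 87.7 ± 25.3 in its clones, and from 3.89 ± 2.31 TPM in WT of 6694c2 to 97.0 ± 19.8 and 237 ± 12.7 in its clones (SD, n = 3 each). Cxcl9 (4.41), Tgtp2 (4.32), Ubd (4.05), Tgtp1 (3.85), Gbp4 (3.62), Cd74 (3.57), H2-Eb1 (3.57), Gvin1 (3.54) and Gbp2 (3.51) completed the largest rises. Epcam fell by 2.53 on the log2 scale (SE 0.18, limma adjusted p = 1.7e-07), from 249 ± 20.9 TPM to 146 ± 55.9 and 26.8 ± 6.96 in 6419c5 and from 25.04 ± 3.38 TPM to 4.64 ± 2.57 and 0.896 ± 0.196 in 6694c2. Reg3b (-2.79), Clic6 (-2.71), Kcnk1 (-2.61), Dio3os (-2.44), Cldn7 (-2.42), the glutathione peroxidase gene Gpx2 (-2.41), Slc16a3 (-2.30) and Cldn6 (-2.29) fell as well. The hemoglobin gene Hba-a2 (-3.17, limma adjusted p = 0.0245) had the largest fall, but it is uncertain: it lost its call without 6419c5 WT replicate 1 (-2.98, adjusted p = 0.0584), without 6419c5 WT replicate 2 (-3.07, adjusted p = 0.0604) and without 6694c2 WT replicate 2 (-2.57, adjusted p = 0.0726).

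Of 21 interferon gamma response genes 18 rose over both lines and none fell (19 and 0 adjusted over the list alone, median 2.28, camera adjusted p = 2e-28, 0.00813 with an estimated correlation). Of 28 type I interferon response genes 27 rose (27 adjusted over the list alone, median 1.23, camera adjusted p = 8.76e-27, 0.0213 with an estimated correlation). Zbp1 rose by 2.47. Of 20 MHC class I genes 18 rose (18 adjusted over the list alone, median 1.66, camera adjusted p = 1.77e-24, 0.00813 with an estimated correlation). Psmb9 was at 3.16, H2-Q7 at 3.01, Tap1 at 2.89 and Nlrc5, the transactivator gene of this class, at 2.61. Epithelial genes fell in 14 of 19 cases (14 adjusted over the list alone, median -0.95, camera adjusted p = 2.09e-18, 0.0152 with an estimated correlation). Basal-like and squamous genes fell in 5 of 8 cases (5 adjusted over the list alone, median -0.72, camera adjusted p = 6.32e-10, 0.0114 with an estimated correlation). St14 (-1.42), Cldn4 (-1.39), Lama3 (-1.90) and Lamb3 (-1.62) were among these. Keratins 8 and 18, the most abundant keratins of simple epithelium, did not pass (Krt8 -0.11, limma adjusted p = 0.34, Krt18 -0.17, adjusted p = 0.148). These 5 lists are the ones that held over both lines with an estimated correlation. The macrophage index stood above WT in clone A of both lines and far below it in clone B of 6419c5. In that clone the interferon and MHC class I genes were nonetheless 0.65 above WT and the epithelial genes -1.63 from WT on the mean log2 scale. In clone B of 6419c5 alone 11 of 31 lists passed at the preset correlation and 0 with the estimated one. Interferon gamma response and epithelial genes were then at adjusted p = 0.0588, MHC class I genes at 0.343 and type I interferon response genes at 0.653.

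Further lists passed camera over both lines at the preset correlation and not with the estimated one. Fry called 20 of 31 lists over both lines. Classical subtype genes fell in 11 of 23 cases, with 1 higher (13 and 1 adjusted over the list alone, median -0.56, camera adjusted p = 1.16e-07, adjusted p = 0.0646 with an estimated correlation). Tff2 (-1.58) and Spdef (-1.37) were among them. Immediate early and dissociation genes fell in 11 of 22 (12 adjusted over the list alone, median -0.32, camera adjusted p = 1.92e-10, adjusted p = 0.0646 with an estimated correlation). Egr3 was at -1.44 and Hspa1a at -1.12. Of 14 EGFR family and ligand genes 6 fell and 1 rose (6 and 1 adjusted over the list alone, median -0.24, camera adjusted p = 1.47e-04, adjusted p = 0.0785 with an estimated correlation). Areg (-1.27) and Ereg (-0.92) were among those that fell. Of 17 genes of ERK pathway output 6 fell and 1 rose (7 and 1 adjusted over the list alone, median -0.26, camera adjusted p = 5.6e-06, adjusted p = 0.083 with an estimated correlation). The phosphatase genes Dusp4 (-0.88) and Dusp5 (-0.61) fell most. Hypoxia genes fell in 7 of 25 cases (8 adjusted over the list alone, median -0.14, camera adjusted p = 7.09e-06, adjusted p = 0.0731 with an estimated correlation). Glycolysis genes fell in 4 of 18 cases (5 adjusted over the list alone, median -0.08, camera adjusted p = 2.71e-05, adjusted p = 0.127 with an estimated correlation). KLF factors fell in 4 of 11 cases (5 adjusted over the list alone, median -0.17, camera adjusted p = 7.35e-05, adjusted p = 0.0785 with an estimated correlation), Klf9 (-0.38) and Klf13 (-0.31) beside Klf5. TGF-beta and SMAD targets fell in 4 of 19, with 1 higher (5 and 1 adjusted over the list alone, median -0.09, camera adjusted p = 0.0049, adjusted p = 0.138 with an estimated correlation). Cholesterol synthesis genes fell in 2 of 22 cases (2 adjusted over the list alone, median -0.13, camera adjusted p = 1.86e-04, adjusted p = 0.332 with an estimated correlation). Unfolded protein response genes fell in 4 of 20 cases, with 2 higher (median -0.07, 4 and 2 adjusted over the list alone, camera adjusted p = 0.0264, adjusted p = 0.197 with an estimated correlation). Proliferation genes fell in 2 of 30 cases (1 adjusted over the list alone, median -0.00, camera adjusted p = 0.0167, adjusted p = 0.626 with an estimated correlation). Of 24 oxidative phosphorylation genes 6 rose, with 9 higher and 1 lower adjusted over the list alone (median 0.13, camera adjusted p = 0.0393, adjusted p = 0.626 with an estimated correlation). The scaling moved the small medians over both lines. With median-of-ratios scaling they were 0.03 for oxidative phosphorylation, -0.24 for hypoxia, -0.18 for glycolysis, -0.27 for KLF factors, -0.19 for TGF-beta and SMAD targets, -0.23 for cholesterol synthesis, -0.17 for the unfolded protein response and -0.09 for proliferation. With quantile normalization they were 0.07 for oxidative phosphorylation, -0.15 for glycolysis, -0.16 for TGF-beta and SMAD targets, -0.14 for the unfolded protein response and -0.10 for proliferation. Without the 20 most abundant genes they were 0.06 for oxidative phosphorylation, -0.21 for hypoxia, -0.15 for glycolysis, -0.16 for TGF-beta and SMAD targets, -0.20 for cholesterol synthesis, -0.14 for the unfolded protein response and -0.07 for proliferation. The proliferation median was 0.03 with the macrophage index as a covariate. Without 6419c5 WT replicate 3, 6694c2 clone A replicate 1 and clone B replicate 3 it was -0.03, and that of the unfolded protein response -0.02.

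Of the markers of other cell types over both lines, T and NK cell genes rose in 6 of 9 cases (7 adjusted over the list alone, median 0.86, camera adjusted p = 1.87e-04, adjusted p = 0.0785 with an estimated correlation). Fibroblast genes rose in 6 of 20 cases (14 adjusted over the list alone, median 0.71, camera adjusted p = 2.71e-05, adjusted p = 0.293 with an estimated correlation). Neutrophil genes rose in 4 of 14 cases (7 adjusted over the list alone, median 0.57, camera adjusted p = 0.0208, adjusted p = 0.239 with an estimated correlation). Macrophage and dendritic cell genes rose in 5 of 22 cases (5 adjusted over the list alone, median 0.47, camera adjusted p = 0.0326, adjusted p = 0.717 with an estimated correlation), and 4 of the 5 were the MHC class II genes named for 6694c2. Endothelial genes rose in 4 of 13, with 1 lower (4 and 1 adjusted over the list alone, median 0.68, camera adjusted p = 0.0396, adjusted p = 0.626 with an estimated correlation). Erythroid genes fell in 4 of 5 cases (4 adjusted over the list alone, median -1.14, camera adjusted p = 2.61e-04, adjusted p = 0.127 with an estimated correlation). With the macrophage index as a covariate the median of macrophage and dendritic cell genes was 0.08. Without 6419c5 WT replicate 3, 6694c2 clone A replicate 1 and clone B replicate 3 that of fibroblast genes was 0.46. The remaining lists did not pass camera over both lines. These were H3K9 methylation enzymes (2 of 18 higher, Kdm4a at 0.24 and Kdm3b at 0.20, adjusted p = 0.786), chemokines and cytokines (6 higher and 5 lower of 30, adjusted p = 0.786), and NF-kB targets (4 and 2 of 20, adjusted p = 0.804). They were also mesenchymal genes (7 and 3 of 20, adjusted p = 0.647), p53 targets (3 and 1 of 19, adjusted p = 0.753), skeletal muscle (0 of 6, adjusted p = 0.146), adipocyte (3 and 1 of 5, adjusted p = 0.976) and keratinocyte markers (0 and 1 of 5, adjusted p = 0.507). Among the chemokine and cytokine genes Cxcl10 (3.16), Ccl5 (2.39) and Csf1 (1.59) rose and Csf2 (-1.22) fell.

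In all, 2473 genes changed over both lines by limma, 1682 higher and 791 lower. Of these, 244 rose and 130 fell at least 2-fold. Other scalings moved the balance here too, to 951 higher and 1360 lower with median-of-ratios scaling, 864 and 1320 with quantile normalization, and 1151 and 1137 without the 20 most abundant genes. With the clone as the unit (6 group means, 3 residual degrees of freedom), limma called 0 genes, with 844 at an unadjusted p under 0.05 and a lowest adjusted p of 0.219.

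**Figure D2:**
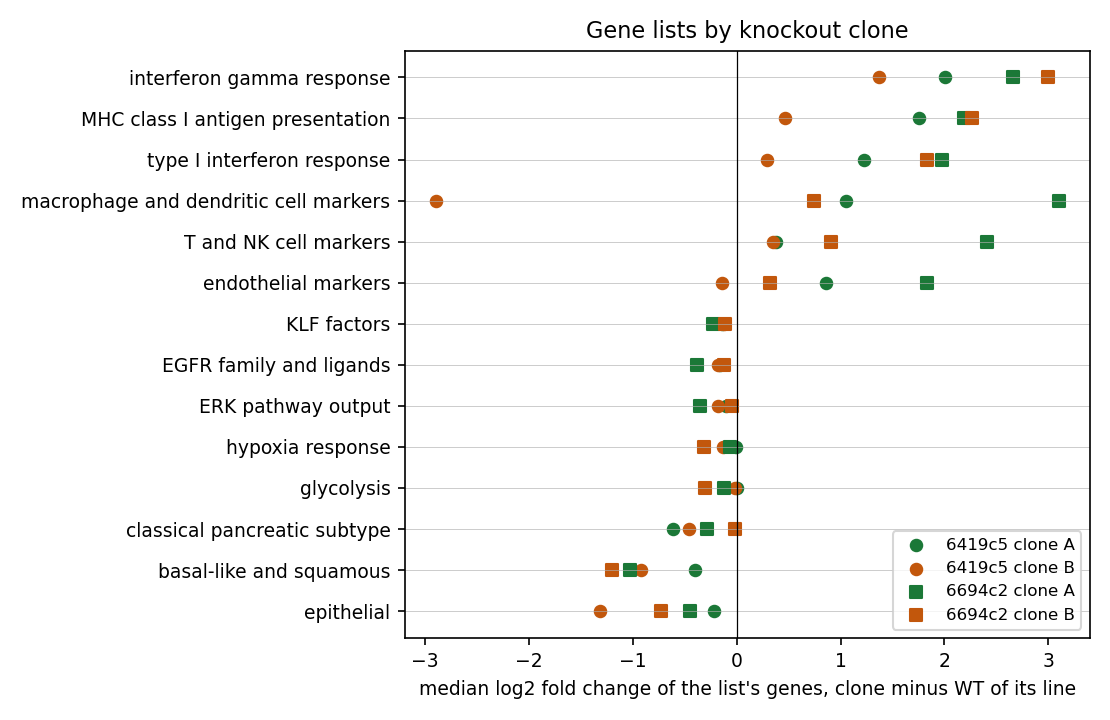
Median log2 fold change against WT of 14 gene lists in each of the 4 knockout clones, on the log2(TPM + 1) scale. The interferon and MHC class I lists lie above 0 and the epithelial list below 0 in all 4 clones.

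Whether the knockout effect differed between lines was tested directly, and 1169 genes passed by limma, 776 with a more positive effect in 6694c2 and 393 with a more negative one. The test rests on the spread between libraries. With 2 clones per line it cannot tell a difference between lines from one between their clones. The clones of 6419c5 alone differed in 3534 genes. The gastric gene Gkn3 (difference 4.39, SE 0.47, limma adjusted p = 5.78e-05) and Olfm4 (4.63, adjusted p = 9.11e-06), a marker of crypt progenitors, fell in 6419c5 and did not in 6694c2. Olfm4 rose there instead, by 2.65 in clone A and 1.54 in clone B. Retnla (5.55) and Ear2 (4.63), which macrophages and eosinophils express, also had a higher effect in 6694c2. Piezo2 (-4.29, SE 0.23, limma adjusted p = 8.81e-08), Ube2e2 (-3.52) and the transcription factor gene Sall1 (-2.78) had a lower one. Mir6395 (4.36), Mir7013 (-3.66) and Mir5103 (-3.63) passed too, but are uncertain. Of the 18 fits that left out 1 library, 15 ended the call of Mir6395 (limma adjusted p from 0.0534 to 0.116) and 13 that of Mir7013 (adjusted p from 0.0526 to 0.132). Mir6395 passed only without 6419c5 clone A replicate 1, 6419c5 clone B replicate 3 or 6694c2 WT replicate 3. Mir7013 passed only without 6419c5 WT replicate 1, 6419c5 clone B replicate 3, 6694c2 WT replicate 1, 6694c2 clone A replicate 2 or 6694c2 clone B replicate 1. Mir5103 lost it without 6419c5 WT replicate 3 (-2.97, limma adjusted p = 0.0662) and without 6694c2 WT replicate 3 (-3.18, adjusted p = 0.0506). By list, 14 of 20 MHC class I genes had a more positive effect in 6694c2 (16 adjusted over the list alone, median 1.19, camera adjusted p = 2.1e-11, adjusted p = 0.201 with an estimated correlation), H2-Q7 at 2.99 and Psmb9 at 2.47. So had 14 of 28 type I interferon response genes (24 adjusted over the list alone, median 0.95, camera adjusted p = 2.08e-11, adjusted p = 0.201 with an estimated correlation). Macrophage and dendritic cell genes moved the same way, 7 of 22 (19 adjusted over the list alone, median 2.84, camera adjusted p = 2.71e-08, adjusted p = 0.388 with an estimated correlation). Of the 7, 4 were the MHC class II genes Cd74, H2-Aa, H2-Ab1 and H2-Eb1. The list median was 0.41 with the macrophage index as a covariate and 1.54 without 6419c5 WT replicate 3, 6694c2 clone A replicate 1 and clone B replicate 3. Of 23 classical subtype genes 7 had a more positive effect in 6694c2, Gkn1 (3.98), Tff2 (2.96) and Foxa1 (2.30) among them. That list had 10 more positive and 2 more negative adjusted over the list alone and camera adjusted p = 0.101 for that list. Of 31 lists 14 passed at the preset correlation and 0 with the estimated one, where fry called 12. Without 6419c5 WT replicate 3 the count was 752, and without the 3 libraries that stood apart 765. Median-of-ratios scaling gave 533 higher and 768 lower (median of all genes moved by -0.15), quantile normalization 416 and 763 (moved by -0.20), and removal of the 20 most abundant genes 631 and 525.

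The overlap of the lines was counted among genes called in each. There were 245 genes higher in both lines, where independent lists would share 78.1, and 149 lower in both, where they would share 26.5. There were 51 that went opposite ways, where 97.8 would. Iigp1, Cxcl9, Ubd and Epcam are among the shared genes. The lines share no libraries. Across the 13422 genes, which are not independent replicates, the fold changes of the lines had a Pearson r of 0.26 and a Spearman rho of 0.148. In all 4 clones, each tested alone against its WT, 95 genes were higher and 33 lower, where independent lists would share 0.523 and 0.0669. Simulated unchanged groups, in which almost no gene is called, shared 0. Simulated clones with shrunk changes on unrelated genes shared a mean of 8.20 higher and 0.95 lower (at most 12 and 4), where independent lists of their size would share 2.33 and 0.227. With changes as estimated they shared 14.45 and 1.45. Part of the excess may come from the WT libraries that the clones of a line share.

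**Figure D3:**
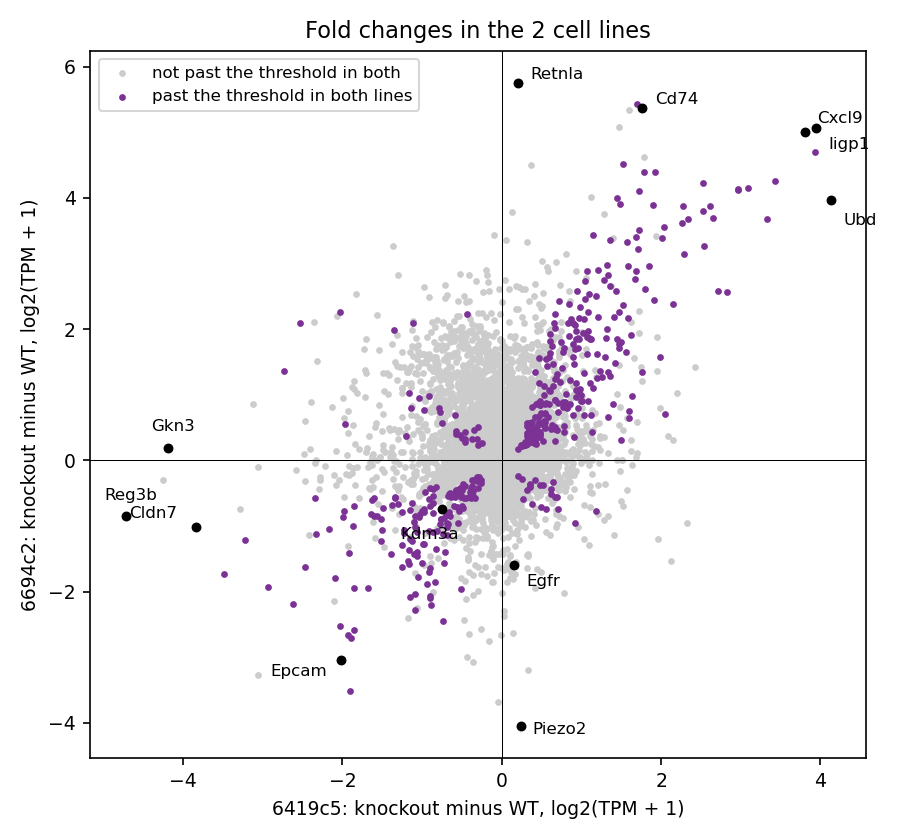
Change of each tested gene with Kdm3a knockout in 6419c5 (x axis) and in 6694c2 (y axis), both on the log2(TPM + 1) scale; purple points passed the test in both lines and black points carry gene names. Cxcl9, Iigp1 and Ubd lie high on both axes, Retnla and Piezo2 on the 6694c2 axis, and Reg3b, Gkn3 and Cldn7 mainly on the 6419c5 axis.

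Within 6419c5 the clones differed from each other in 3534 genes by limma, 991 higher and 2543 lower in clone B than in clone A. Clone B had fewer transcripts of macrophages, of interferon-induced genes and of epithelium. All 22 macrophage and dendritic cell genes were lower in it (22 adjusted over the list alone, median -3.70, camera adjusted p = 7.68e-09, adjusted p = 0.423 with an estimated correlation). The named falls were largely of that kind, with Ccl8 (-6.55, SE 1.22, limma adjusted p = 0.00149), from 2588 ± 1445 TPM in clone A to 25.9 ± 14.2 in clone B (SD, n = 3 each). Clec10a (-5.95), Folr2 (-5.75), Cd209f (-5.69) and the uncertain class I gene H2-Q8 (-5.59) were lower too. Of 21 interferon gamma response genes 19 were lower in clone B (19 adjusted over the list alone, median -0.94, camera adjusted p = 9.28e-09, adjusted p = 0.148 with an estimated correlation). So were 13 of 19 epithelial genes (13 adjusted over the list alone, median -1.01, camera adjusted p = 6.08e-06, adjusted p = 0.212 with an estimated correlation), Spint1 (-2.92) and Cldn4 (-2.64) among them. All 6 skeletal muscle genes were lower (6 adjusted over the list alone, median -2.17, camera adjusted p = 3.97e-04, adjusted p = 0.251 with an estimated correlation). Hsd3b1 (3.31, SE 0.24, limma adjusted p = 7.97e-07), a steroid-making enzyme gene, Tff2 (3.03), Twist1 (2.45), a transcription factor of mesenchymal cells, and Sprr2a2 (2.40) were higher in clone B. Against WT, 163 genes rose and 122 fell in both clones of 6419c5. Independent lists would share 33.6 and 24.2, and simulated unchanged groups, in which almost no gene is called, shared 0. Simulated clones with shrunk changes on unrelated genes and shared WT libraries had a mean of 126 genes higher and 73.9 lower in both (at most 144 and 87), where independent lists of their size would share 82.1 and 48.2. With changes as estimated they had 185 and 107. Part of the excess may thus come from the shared WT libraries, which are too few to be split. Median-of-ratios scaling gave 1566 genes higher and 1925 lower in clone B, quantile normalization 1985 and 1635 (median of all genes moved by 0.15), and removal of the 20 most abundant genes 1471 and 2125. With the macrophage index as a covariate the count was 1390 and the median of macrophage and dendritic cell genes -0.04. Ccl8 (-1.15, limma adjusted p = 0.0595), Clec10a (-1.07, adjusted p = 0.0667), Folr2 (-0.59, adjusted p = 0.117) and Cd209f (-0.29, adjusted p = 0.692) then no longer passed.

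Within 6694c2 the clones differed in 1279 genes by limma, 707 higher and 572 lower in clone B. On average clone B had more transcripts of dividing cells and fewer of macrophages, neutrophils, T and NK cells, fibroblasts and endothelium. Of 30 proliferation genes 17 were higher in it (26 adjusted over the list alone, median 0.68, camera adjusted p = 9.21e-16, adjusted p = 0.182 with an estimated correlation), Top2a by 1.11 and Mki67 by 0.93. Of 22 cholesterol synthesis genes 7 were higher (14 adjusted over the list alone, median 0.56, camera adjusted p = 2.86e-07, adjusted p = 0.263 with an estimated correlation). The mucin genes Muc5ac (1.89) and Muc5b (1.79, SE 0.24, limma adjusted p = 8.41e-04), the protocadherin gene Pcdhgb2 (2.16) and the adenosine receptor gene Adora1 (1.90) were higher in clone B. Neutrophil genes were lower in 10 of 14 cases (10 adjusted over the list alone, median -1.72, camera adjusted p = 2.93e-12, 0.0136 with an estimated correlation), S100a9 by -2.83 and Mmp9 by -2.83. Of 30 chemokine and cytokine genes 10 were lower and 3 higher (11 and 4 adjusted over the list alone, median -0.50, camera adjusted p = 3.48e-04, 0.015 with an estimated correlation). Cxcl2 (-2.39) and Il1b (-2.18) were among those lower. Fibroblast genes were lower in 10 of 20 cases (17 adjusted over the list alone, median -1.76, camera adjusted p = 7.28e-12, adjusted p = 0.183 with an estimated correlation), Dcn by -2.45. Macrophage and dendritic cell genes had the lowest median of these lists, with 3 of 22 lower (17 adjusted over the list alone, median -2.13, camera adjusted p = 3.95e-09, adjusted p = 0.292 with an estimated correlation). For macrophages and fibroblasts the gap came from clone B replicates 1 and 2. Replicate 3 had a macrophage index of 7.799 and summed fibroblast markers of 1226.4 TPM, within the 7.7905 to 8.4313 and 1101.8 to 1551.3 TPM of clone A. Endothelial genes were lower in 7 of 13 cases (10 adjusted over the list alone, median -1.51, camera adjusted p = 8e-07, adjusted p = 0.263 with an estimated correlation). T and NK cell genes were lower in 4 of 9 (6 adjusted over the list alone, median -1.10, camera adjusted p = 1.92e-06, adjusted p = 0.0577 with an estimated correlation). The RNase gene Rnase2a (-3.74), Mgp (-3.37), an inhibitor of calcification, and the granzyme gene Gzmc (-2.89) were lower too. Mir6369, Mir142b and Mir212 passed the test but are listed at 0 in all libraries of 1 of the clones, so no fold is given. Each also lost its call when single libraries were left out. Mir6369 did so without clone B replicate 1 (limma adjusted p = 0.0934), Mir142b without clone A replicate 3 (adjusted p = 0.107) and Mir212 without clone B replicate 2 (adjusted p = 0.0723). Against WT, 771 genes rose and 334 fell in both clones of 6694c2. Independent lists would share 209 and 37.1, and simulated unchanged groups, in which almost no gene is called, shared 0. Simulated clones with shrunk changes on unrelated genes and shared WT libraries had a mean of 518 and 84.3 (at most 587 and 115), where independent lists of their size would share 381 and 63.3. With changes as estimated they had 648 and 102. Part of the excess may thus come from the shared WT libraries. Single libraries moved the difference between these clones widely. The count was 669 without clone A replicate 2, 557 without clone A replicate 3, 343 without clone B replicate 1 and 342 without clone B replicate 2. It was 382 with the macrophage index as a covariate, which gave medians of 0.42 for proliferation, 0.37 for cholesterol synthesis, -0.30 for chemokines and cytokines, -1.11 for fibroblast, -0.62 for T and NK cell and -0.09 for macrophage and dendritic cell genes. Without 6694c2 clone A replicate 1 and clone B replicate 3 (and 6419c5 WT replicate 3) the median of chemokines and cytokines was -0.33 and that of endothelial genes -0.86. Median-of-ratios scaling gave 489 genes higher and 618 lower in clone B, a mean of at least 5 TPM gave 626 and 314, and only the libraries of the groups compared gave 829 and 427.

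**Figure D4:**
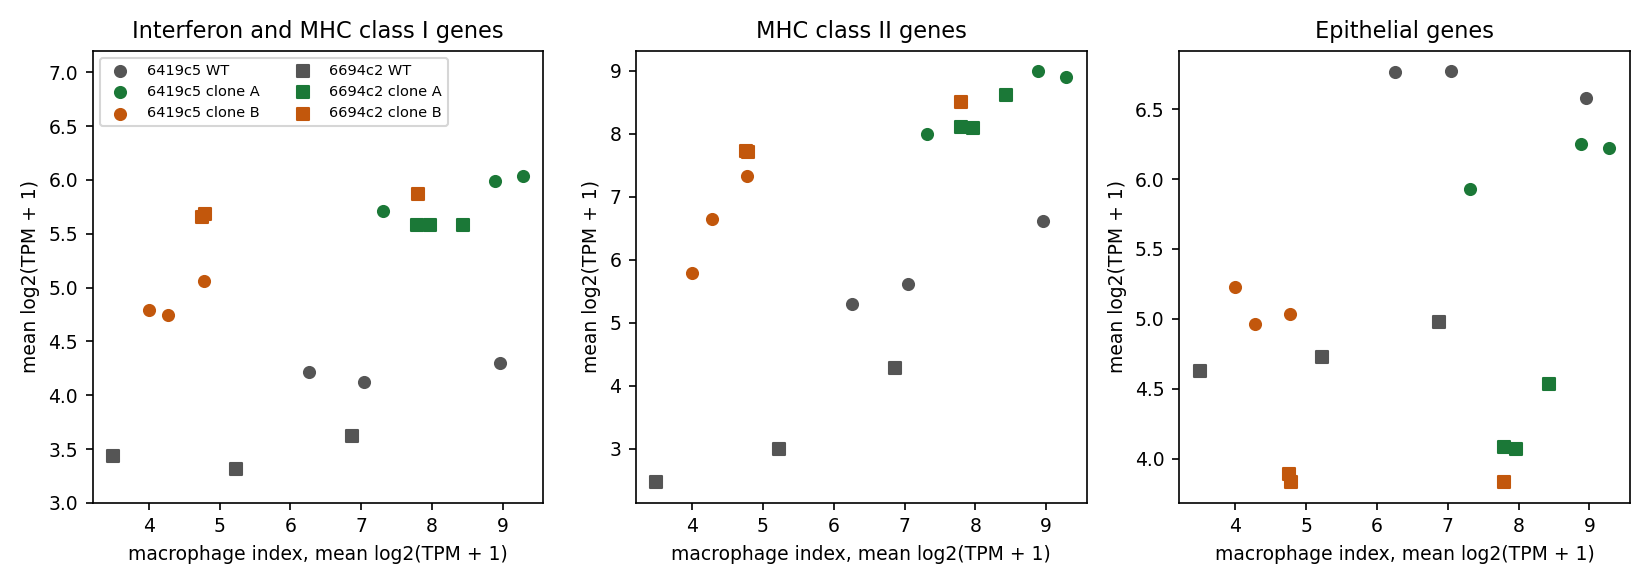
Mean log2(TPM + 1) per library of 69 interferon and MHC class I genes, of the MHC class II genes and of 19 epithelial genes (y axes) against the macrophage index of the same library (x axis). The libraries of 6419c5 clone B lie at the lowest index values of their line, with interferon and MHC class I means above those of WT and epithelial means below.

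The WT groups show how the lines differed without a knockout. They differed in 6213 genes by limma, 1894 higher and 4319 lower in 6694c2 than in 6419c5. The cell cycle inhibitor genes Cdkn2a and Cdkn2b, neighbors in the genome, were at 503.5 ± 24.6 and 110.5 ± 9.15 TPM in 6419c5 (SD, n = 3). In 6694c2 Cdkn2a is listed at 0 in all 3 WT libraries and Cdkn2b was at 0.043 ± 0.075 TPM. Rhox5 (-6.40, SE 0.12, limma adjusted p = 4.74e-14), Gkn3 (-6.94) and the membrane protein gene Tm4sf5 (-6.37) were also lower in 6694c2. The VEGF receptor gene Flt1 went the other way, at 1.07 ± 0.189 TPM in 6419c5 and 79.6 ± 6.37 TPM in 6694c2 (5.29, SE 0.15, limma adjusted p = 6.11e-12), with Mgp (4.16), Krt14 (4.01) and Tlcd2 (3.89). Hypoxia genes were higher in 6694c2 in 22 of 25 cases (23 adjusted over the list alone, median 1.11, camera adjusted p = 2.44e-18, 0.00672 with an estimated correlation). Adm was higher by 2.25, Slc2a1 by 2.01 and P4ha2 by 1.65. Glycolysis genes were higher in 14 of 18, with 1 lower (14 and 1 adjusted over the list alone, median 0.89, camera adjusted p = 8.65e-12, adjusted p = 0.0801 with an estimated correlation). Epithelial genes were lower in 18 of 19 (18 adjusted over the list alone, median -1.96, camera adjusted p = 2.08e-07, adjusted p = 0.311 with an estimated correlation). Cldn7 was at -3.46, Epcam at -3.27 and Krt7 at -2.85. Macrophage and dendritic cell genes were lower in 15 of 22 cases (19 adjusted over the list alone, median -2.29, camera adjusted p = 0.00923, adjusted p = 0.82 with an estimated correlation), and their median was -0.18 with the macrophage index as a covariate. The balance of directions depended on the scaling, with 2883 higher and 2894 lower with median-of-ratios scaling (median of all genes moved by 0.19) and 3242 and 2568 with quantile normalization (moved by 0.27).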

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

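In this part the tests of macrophage share per clone, of macrophages of constant content and of dilution by other cells were chosen only after the result was seen, and so was the use of the macrophage index as a covariate, while the explanations by macrophages in the sorted cells, by dendritic cells and by abundant transcripts were written before the data were examined. The direct test of the knockout effect between the lines set apart 1169 genes by limma, so a sum over both lines can hide effects seen in 1 line. The test rests on the spread between libraries. With 2 clones per line it cannot tell a difference between lines from one between their clones. Among the named genes of 6419c5, a difference between the lines singled out Gbp4 (difference of 6694c2 minus 6419c5 on the log2 scale 1.07, limma adjusted p = 0.00941), Gbp3 (1.04, adjusted p = 0.0171), Reg3b (3.87, adjusted p = 0.00316), Reg1 (3.96, adjusted p = 0.0249), Gkn3 (4.39, adjusted p = 5.78e-05), Cldn7 (2.82, adjusted p = 1.62e-04), Kcnk1 (1.75, adjusted p = 0.00277), Reg3g (2.54, adjusted p = 0.0367), Gabrp (2.01, adjusted p = 2.04e-04), Gkn1 (3.98, adjusted p = 3.36e-04), Tff2 (2.96, adjusted p = 4.14e-05) and Dio3os (1.01, adjusted p = 0.00646).

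Among the named genes of 6694c2 the same limma test singled out Retnla (5.55, adjusted p = 0.00616), H2-Eb1 (3.73, adjusted p = 0.00298), Cd74 (3.61, adjusted p = 0.00289), H2-Aa (3.73, adjusted p = 0.00364), H2-Ab1 (3.61, adjusted p = 0.00993) and H2-Q7 (2.99, adjusted p = 1.58e-05), whose effect was more positive there. It also singled out Piezo2 (-4.29, adjusted p = 8.81e-08), the uncertain Mir5103 (-3.63, adjusted p = 0.0206), Clic6 (-1.62, adjusted p = 2.07e-04), Ube2e2 (-3.52, adjusted p = 4.24e-06), Kctd15 (-2.71, adjusted p = 1.33e-05), Trib2 (-2.56, adjusted p = 2.02e-05), Slco3a1 (-2.59, adjusted p = 0.00153) and Egfr (-1.74, adjusted p = 0.00103), whose effect was more negative there. Of these last only Clic6 passed in 6419c5 too (-1.90, limma adjusted p = 8.28e-07). Gkn1 and Gkn3, which fell in 6419c5 alone, were at 0.398 and 0.286 TPM in WT of 6694c2, which leaves them little room to fall on this scale.

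The first pattern is the rise of interferon and MHC class I genes (69 genes). A changed amount of macrophages of constant content does not account for it. With the macrophage index as a covariate the median change over both lines was 1.47, and 1.48 without it. In clone B of 6419c5, whose macrophage index was 3.07 below WT (-3.07), the mean of these genes was 0.65 above WT (SD within groups 0.13) and its lowest library 0.45 above the highest WT library. These are spreads between libraries: none of these 3 lists passed in that clone with an estimated correlation. Removing the 20 most abundant genes left the median at 1.47, so a shift of scale by a few transcripts is not the source. The index was read as the amount of macrophages, but its genes may also change with the state of the macrophages. Macrophages activated by interferon, or other immune cells, are therefore not excluded. What raised these genes was not tested and stays open.

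The second pattern is the rise of the MHC class II genes Cd74, H2-Aa, H2-Ab1, H2-Eb1 and Ciita. Relative to the macrophage index their mean was 1.71 above WT in the lowest of the 4 clones and 4.15 in the highest (SD within groups 0.74). In the 3 clones whose own mean rose by more than 2 SDs, this excludes macrophages of constant content as the whole source. It does not exclude macrophages activated by interferon. In clone B of 6419c5 the relative value (3.818) came mostly from a macrophage index of -3.07 from WT, so it shows no rise there. Macrophages of constant content would have lowered the MHC class II mean with the index, but that mean was 0.749 above WT. Relative to the index the lowest library of clone B (1.792) lay above the highest WT library (-0.957). These values argue against macrophages of constant content as the whole source of these transcripts in that clone. In clone B of 6419c5 only Ciita of the 5 passed alone (1.65, limma adjusted p = 7.26e-04). Dendritic cells cannot be told apart from tumor cells as a source: the mean of 7 dendritic cell genes (median 1.98 TPM) was at least 0.47 above WT in the 3 clones whose MHC class II mean rose by more than 2 SDs (SD within groups 0.28), but -0.40, -1.82 and -0.11 from WT relative to the macrophage index. In clone B of 6419c5 the mean of the dendritic cell genes was -0.235 from WT, but 2.835 above WT relative to the macrophage index. Cd209a (6.34 TPM in WT, 0.397 in clone B) and Batf3 (2 and 0.738 TPM) were lower there, and the other genes of the 7 higher. The MHC class II mean, 0.749 above WT, lay within 2 SDs of 0.65, so dendritic cells cannot be judged in that clone.

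The third pattern is the fall of epithelial genes (19 genes). Dilution by macrophages does not account for it in clone B of 6419c5, which had the fewest macrophage transcripts of its line. There the mean was -1.63 from WT (SD within groups 0.17) and the highest library -1.35 from the lowest WT library. Dilution would also lower all members alike, but the mean change of Krt8 and Krt18 over both lines was -0.14, against a median of -0.95 for the list. The epithelial list did not pass in that clone with an estimated correlation (adjusted p = 0.0588). In clone A of 6419c5 fibroblast genes rose (median 1.03), though not past the threshold with an estimated correlation, and part of the fall of -0.571 may come from dilution. The same holds for clone A of 6694c2, whose epithelial mean was -0.549 from WT with a macrophage index 2.864 above WT. Whether the knockout lowers these genes stays open, since differences between clones cannot be separated from it with 2 clones per line.

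To see whether chance can be excluded, the libraries were also regrouped at random, in 100 splits each. The splits mix libraries of different clones, so at most they test the grouping of libraries and not that of clones. With the clone as the unit limma called 0 genes over both lines (844 at an unadjusted p under 0.05, lowest adjusted p 0.219), so chance differences between clones cannot be excluded for any of these counts. For 6419c5, 3 splits with the real one had as many changed genes (990 real, 3649 the highest other) and 3 as many genes shared by both clones (285 real, 1777 the highest other). The splits with 3649 and 3198 genes took all 3 libraries of clone B as controls, so they point to a structure of the samples: clone B stands apart from the other libraries of its line. For lists in 6419c5, 20 splits had as many (14 real, 16 the highest other), and for lists in 6694c2 7 had as many (21 real, 22 the highest other), so chance cannot be excluded for these 2 counts. The median other split called 10 lists in 6419c5, 13 in 6694c2 and 13 over both lines, so many lists also pass at the preset correlation in mixed groups. For 6694c2 only the real split, 1 of 100, reached its changed genes (2744 real, 2210 the highest other) and its genes shared by both clones (1105 real, 938 the highest other). The split with 2210 and 938 kept all 3 WT libraries as controls, so it is no regrouping of WT and knockout. Likewise 1 of 100, the real one, reached the count over both lines for changed genes (2473 real, 583 the highest other), for lists (23 real, 22 the highest other), for the difference between lines (1169 real, 58 the highest other) and for the overlap of the lines (394 real, 0 the highest other). For each gene count, over both lines and within each line, the median other split was at 0. Groups that mix WT and knockout libraries have a wider spread, so few genes can pass in them. The overlap of 0 in the other splits was therefore nearly set in advance and says little on chance. For the clones of 6419c5 (3534 real, 2 the highest other), the clones of 6694c2 (1279 real, 6 the highest other) and the WT lines (6213 real, 1464 the highest other), 10 splits are too few to exclude chance.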

How the results depend on the processing

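The macrophage covariate and the removal of 3 libraries together (6419c5 WT replicate 3, 6694c2 clone A replicate 1 and clone B replicate 3) were chosen only after the result was seen, and limma's array weights were computed gene by gene after the planned method did not converge. Pseudocount, filter and scaling left the total of each count within 1.5 times the main one, though the balance of higher and lower genes moved. Median-of-ratios scaling brought Smad4 in 6694c2 past the threshold (-0.36, limma adjusted p = 0.0134). Among the knockouts, the fall of Kdm3a over both lines ranged from -0.84 to -0.62 when each library was left out in turn. Changed genes ranged from 686 to 972 in 6419c5, from 1962 to 2809 in 6694c2 and from 1827 to 2545 over both lines. The line difference ranged from 752 to 1252, clone B minus A from 2388 to 3485 in 6419c5 and from 342 to 1857 in 6694c2, and WT lines from 5377 to 6177. Genes shared by both clones ranged from 206 to 252 in 6419c5 and from 802 to 1214 in 6694c2, the overlap of lines from 290 to 415, and lists from 11 to 14 in 6419c5, 19 to 22 in 6694c2 and 18 to 23 over both. With only the libraries of the groups compared the WT lines differed in 3952 genes, against 6213 in the main fit. The knockout of 6694c2 then changed 2104 genes, against 2744. The clones differed in 3313 genes in 6419c5 (main fit 3534) and in 1256 in 6694c2 (main fit 1279). These fits had fewer samples too, so fewer samples alone do not explain the drop between the WT lines. Array quality weights, which are low for libraries far from their group, ran from 0.1894 to 1.821 in WT libraries. In knockout libraries they ran from 0.4259 to 4.596. The spread shared by all groups may thus be too small for comparisons with WT, and their adjusted p-values too low. Whether this caused the drop was not tested. With the clone as the unit limma called 0 genes (844 at an unadjusted p under 0.05), and Kdm3a was at -0.75 (adjusted p = 0.601), with fewer units. The replicate numbers do not pair the libraries (same-numbered pairs were best in 3 of 18 cases). As a block they gave 823 genes for the clones of 6694c2 and 3765 for the WT lines, and Kdm3a in 6419c5 lost its call (adjusted p = 0.0544). Array weights gave 4475 genes in 6694c2, 2188 for the line difference, 6184 and 5926 for the clones of 6419c5 and 6694c2, and 2152 shared by both clones of 6694c2, and the cause was not tested. An adjusted p under 0.01, a stricter threshold, gave 518, 1332 and 1262 changed genes in 6419c5, 6694c2 and over both, 439 for the line difference, 2057 and 396 for the clones of 6419c5 and 6694c2, 144 and 537 shared by both clones, 207 in the overlap and 9 lists in 6419c5. The macrophage covariate gave 1501 genes in 6419c5, and 1390 and 382 for the clones of 6419c5 and 6694c2, and the removal of 3 libraries together gave 765 for the line difference. For these the cause was not tested. Camera with an estimated correlation called 5 lists over both lines, 4 in 6419c5 and 6 in 6694c2. Fry called 20, 9 and 22 in the same order. The cause of these differences was not tested. Smad4, which never passed in the main test, changed sign, in 6419c5 to -0.0852 with the covariate and -0.0601 without the 3 libraries, and in 6694c2 to 0.0255 with the covariate. When each library was left out it went from -0.0601 to 0.1804 in 6419c5 and from -0.1176 to 0.0027 over both lines. For Smad4 the cause was not tested. Among named genes, Muc5ac (limma adjusted p = 0.0503) and Mgp (adjusted p = 0.0554) lost their call between the clones of 6694c2 with only those groups. Depth is unknown, so it is not known which genes with low TPM rest on few reads.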

Other observations

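The following genes were chosen after their values were seen. Rhox5, a homeobox gene of the X-linked reproductive cluster, rose in both knockout clones of 6694c2 and in neither of 6419c5. In 6694c2 it went from 9.99 ± 1.79 TPM in WT to 160.9 ± 5.62 in clone A (3.89 on the log2 scale, limma adjusted p = 1.22e-10) and 76.1 ± 2.20 in clone B (2.82, adjusted p = 2e-09; SD, n = 3 each). In 6419c5 it stood at 916 ± 46.0, 911 ± 142 and 1001 ± 115 TPM, and the difference between lines was 3.31 (limma adjusted p = 2.26e-08). Sall1, at 6.02 ± 1.77 TPM in WT of 6694c2, was at 0.095 and 0.127 TPM in its clones. Cdkn2a stayed near 0 in the knockouts of 6694c2, at 0.278 and 0.175 TPM, and near its WT level in those of 6419c5.

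Ifng, the gene of interferon gamma, was listed at 0 in every WT library and in clone A of 6419c5. Its mean was 0.085 TPM in clone B of 6419c5, and 0.452 ± 0.418 and 0.219 ± 0.268 TPM in clones A and B of 6694c2. It was not tested, because its mean is below 1 TPM. In 6694c2 Muc5ac was at 3.54 ± 0.77 TPM in WT, 8.58 ± 6.30 in clone A and 30.4 ± 4.44 in clone B, and Muc5b at 1.37 ± 0.56, 3.41 ± 1.25 and 14.1 ± 3.09 TPM.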
